A study of Mus musculus with 12 samples.

How the data were processed

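Total RNA from mouse cells was measured on 12 Illumina bead arrays, with 2 arrays in each of 6 groups: embryonic fibroblasts (MEF), embryonic stem cells (ESC), and 4 types of induced pluripotent stem cells (iPSC). Group and replicate names came from the sample titles. Per the labels' protocols, RNA was extracted with a PureLink kit, samples with an integrity number of 7.5 or greater were amplified and labelled with biotin, and each array carried 1 sample in 1 colour. The 2 ESC samples were labelled as different lines, CJ7 and CGR8. The labels did not say whether other replicates were separate clones or cultures, so p-values measure only the spread between these samples. Across genes, the 2 arrays correlated with r of 0.968 in MEFs and 0.976 in M3O-lenti LIF- cells, below the 0.978 between the ESC lines. No arrays are known to be technical repeats, so these values do not show whether the spread there is technical or what differed between the samples. In each of the other 3 iPSC types, 1 of the 2 arrays lacked signal of the Y-linked gene Eif2s3y, so their spread, like that of the ESC lines, includes differences between cells.

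The deposited non-normalized table held a linear intensity per probe and array, and a detection p-value per probe and array, per the file headers. Its values came from GenomeStudio, per the submitters' processing notes; the version and settings were not given in the sources used here. The detection p-values moved in steps that implied 936 negative control probes. The deposited series matrix held intensity values on a linear scale after normalization by the submitters. Each of its columns equalled the non-normalized column multiplied by 1 factor, 0.712 to 1.77, and shifted by 1 constant, with column medians of 91.3 to 94.3. The method behind these factors was not given in the sources used here, so the matrix served only as an alternative.

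That table listed 45281 probes. GEO's platform annotation gave a single gene symbol for 34885 probes, several for 18 and listed no gene for 10378. Symbols were updated through gene IDs with RefSeq's gene names for GRCm38.p6, which matched 34807 probes. No coordinates are given, since the annotation states no genome build; chromosomes and the order of genes served only to group genes. Non-normalized intensities were background-corrected from the detection p-values, given an offset of 16, quantile-normalized and taken to log2 with neqc in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table). Probes were kept with a detection p under 0.01 on both arrays of at least 1 group, which left 16606 probes, 14421 of them with 1 symbol. Each gene was read from its probe with the highest mean over the 12 arrays, which gave 9550 genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

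Each gene was fitted in limma (lmFit and eBayes, 6 residual degrees of freedom) with 1 mean per group over all 12 arrays, and 10 contrasts were tested, two-sided, with Benjamini-Hochberg adjustment over the 9550 genes. A gene was called at an adjusted p under 0.05. Errors printed with log2 differences are standard errors from this fit. A gene whose chosen probe was detected on no array of a group has only a bound there. Both "not detected" and the bound refer to that probe, and other probes of the gene can differ. The fold is then given as "at least". It sets the other group's mean against the higher of each array's lowest detected signal and the probe's own signal. Lists of genes and cell type markers, 29 in each contrast, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 29 lists. The same test with a correlation estimated from the residuals was an alternative, and its adjusted p is given beside calls that it ended. Counts of list members "adjusted over the list alone" came from the same gene tests.

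Groups, contrasts, lists and the genes to be named were fixed before the data were examined. Named genes were the 10 called genes with the largest rises and the 10 with the largest falls in each comparison between iPSC groups, and 5 and 5 in comparisons with ESCs or MEFs. These had to be detected on both arrays of a compared group, with no overlap between the groups' arrays and a symbol that is not a clone name. For each list described, up to 4 members with the smallest adjusted p were added, and a fixed set of pluripotency, LIF signalling and fibroblast genes was followed whatever its result.

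The fit was tested on simulated data over the same 9550 genes, with normal noise of the observed size. For M3O-lenti LIF- over M3O-lenti LIF+, it recovered 41 of 100 genes changed by 1 on the log2 scale and 83 of 100 changed by 2, and called 12 of 9330 unchanged genes. For M3O-lenti LIF- over the mean of the 3 LIF+ groups, it recovered 57 and 97 of 100, and called 8 of 9330 unchanged genes. The adjustment admits larger p-values when more genes change, so these rates hold for the number of genes changed here. Recovery may be lower in the measured comparisons, where fewer genes were called. A simulated list of 20 genes shifted by 0.5 gave camera p-values of 6.5e-14 and 1.61e-12 in these comparisons, and an unshifted list gave 0.154 and 0.459. The simulated noise was independent between genes, so this does not test camera on lists whose members vary together.

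Alternatives were quantile normalization without background correction, the submitters' matrix, no detection filter, all probes with 1 symbol, a 2-fold minimum, only the arrays of the groups compared, a trended and robust variance, the replicate letter as a block, and leaving out each array in turn. Leaving out an array leaves its group with 1 array, which was assumed to vary like the other groups. Probes detected per array numbered 13805 to 15232, and the number of arrays limits the precision. The arrays' slides were not given in the sources used here.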

Results

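Expression was measured in 12 samples of mouse cells: MEFs, ESCs and 4 types of iPSC made from MEFs, with 2 arrays each. O-retro iPSCs received Oct4, Sox2, Klf4 and c-Myc from retroviral vectors. O-lenti iPSCs received Oct4 from a lentiviral vector, which was meant to keep that transgene expressed, and the other factors from retroviral vectors. In M3O-lenti iPSCs, M3O replaced Oct4; M3O is a fusion of Oct4 with the transactivation domain of the muscle regulator MyoD. These 3 types were grown with the cytokine LIF at 1000 U/ml, and ESCs and LIF+ iPSCs were grown on irradiated MEF feeder cells. The fourth type, M3O-lenti LIF-, was made and kept without LIF, and the labels name no feeder cells for it. The LIF status of the ESCs was not labelled. Raw median intensity lay between 85.8 and 94.5 on the 12 arrays. The 95th percentile of raw intensity was 517 on O-retro replicate B and 575 on O-lenti replicate B, and lay between 729 and 1126 elsewhere.

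MEFs stood apart from the pluripotent samples on the first principal component, which held 66.2% of the variance. Their scores were -104 and -115, against 11.8 to 30.6 for the other 10 arrays. The second component, with 12.6%, set the ESC arrays at -35.7 and -47.8. Without MEFs, the first 2 components held 40.7% and 15.1%, and the M3O-lenti LIF- arrays lay apart from each other, at -11.4 and -26.8 for replicate A and at 11.9 and -6.61 for replicate B. Across genes, which are not independent replicates, arrays of 1 group correlated with r of 0.968 (MEF) to 0.984 (M3O-lenti LIF+). Arrays of different iPSC types correlated with r of 0.9607 (M3O-lenti LIF+ A and LIF- A) to 0.9897 (O-lenti B and M3O-lenti LIF+ B). Some were thus closer to each other than replicates were. The A arrays of O-lenti and M3O-lenti LIF+ reached 0.9876, against 0.9776 and 0.9837 within these groups.

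**Figure D1:**
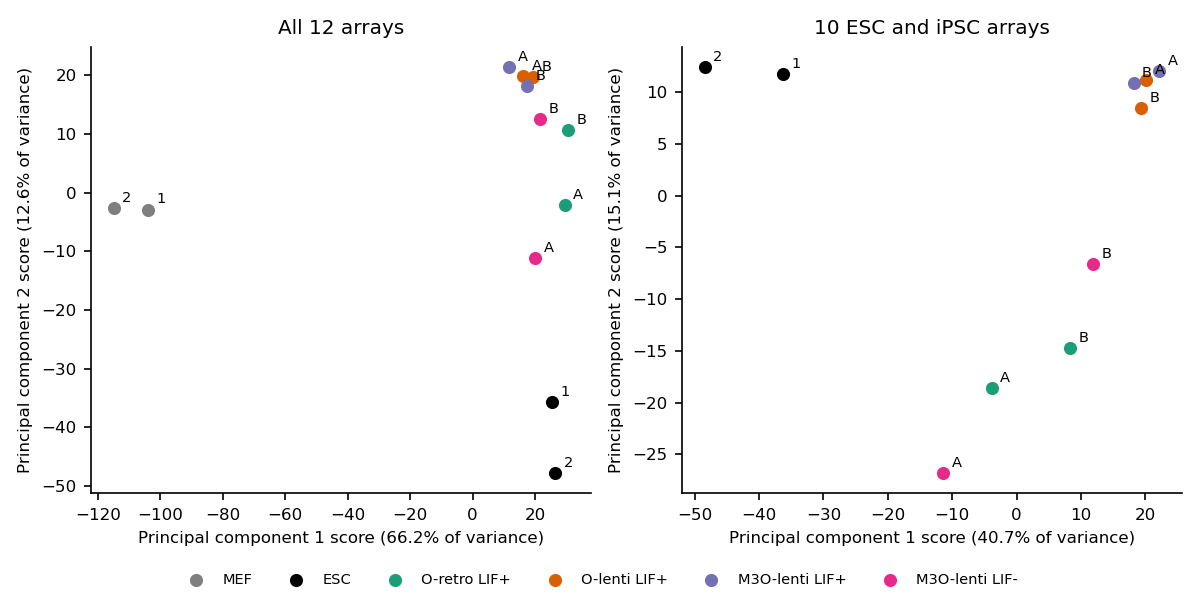
Scores (log2 intensity, centred per gene) on the first 2 principal components for all 12 arrays (left, 66.2% and 12.6% of variance) and for the 10 ESC and iPSC arrays (right, 40.7% and 15.1%). Each point is 1 array, coloured by group and marked with its replicate.

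The comparison of M3O-lenti iPSCs without and with LIF asked which mRNAs go with growth without LIF. Xlr4a, an X-linked gene of a lymphocyte-regulated family, fell by 4.37 ± 0.46 on the log2 scale (adjusted p = 0.0177), from 12.21 ± 0.36 to 7.84 ± 0.17 (SD, n = 2 each). LIF+ A lacked signal of the Y-linked gene Eif2s3y (4.64), unlike LIF+ B (9.02) and the LIF- arrays (8.68 and 9.15). Ly6g6e, which encodes a membrane-anchored Ly6 protein, fell by 2.16 ± 0.27 (adjusted p = 0.0471). Some genes tied to LIF had lower values without LIF and did not pass: Stat3, the transcription factor that LIF activates, differed by -1.56 ± 0.28 (adjusted p = 0.165), its feedback inhibitor Socs3 by -1.67 ± 0.41 (adjusted p = 0.306) and the kinase gene Pim3 by -1.16 ± 0.27 (adjusted p = 0.306). Pou5f1 (0.16 ± 0.36, adjusted p = 0.931), Sox2 (0.28, adjusted p = 0.716) and Nanog (-0.77 ± 0.39, adjusted p = 0.599), which encode core pluripotency factors, did not pass either. Klf4, a LIF target and reprogramming factor, differed by -1.96 ± 0.62 (adjusted p = 0.434); its 2 LIF- arrays lay at 5.95 (replicate A) and 8.54 (replicate B). Otx2, a gene of the primed epiblast, differed by 2.50 ± 0.64 (adjusted p = 0.317), with LIF- arrays at 9.94 and 7.40. Without LIF- B, and so with replicate A as the only LIF- array, Stat3 (-1.96, adjusted p = 0.0253), Klf4 (-3.25, 0.0104) and Otx2 (3.77, 0.0104) passed.

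With limma, 2 of 9550 genes were called, both lower without LIF, and 843 had an unadjusted p under 0.05 where chance would give 478. This excess was gone without LIF- A and larger without LIF- B, fits that leave 1 LIF- array. Both calls were lost without LIF+ A (Xlr4a, adjusted p = 0.474; Ly6g6e, 0.678), without LIF- A (0.283 and 0.298) and without LIF+ B (0.164 for both), while 48 genes were called without LIF- B. Neither gene passed with quantile normalization alone (adjusted p = 0.0702 for both), with the submitters' matrix (0.0569 for both) or without a detection filter (0.155 for both), nor Ly6g6e with only the arrays of the groups compared (0.178). Lif and Myod1 were not detected on any ESC or iPSC array, and Myc was detected on none of the LIF+ arrays and 1 of the LIF- arrays.

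**Figure D2:**
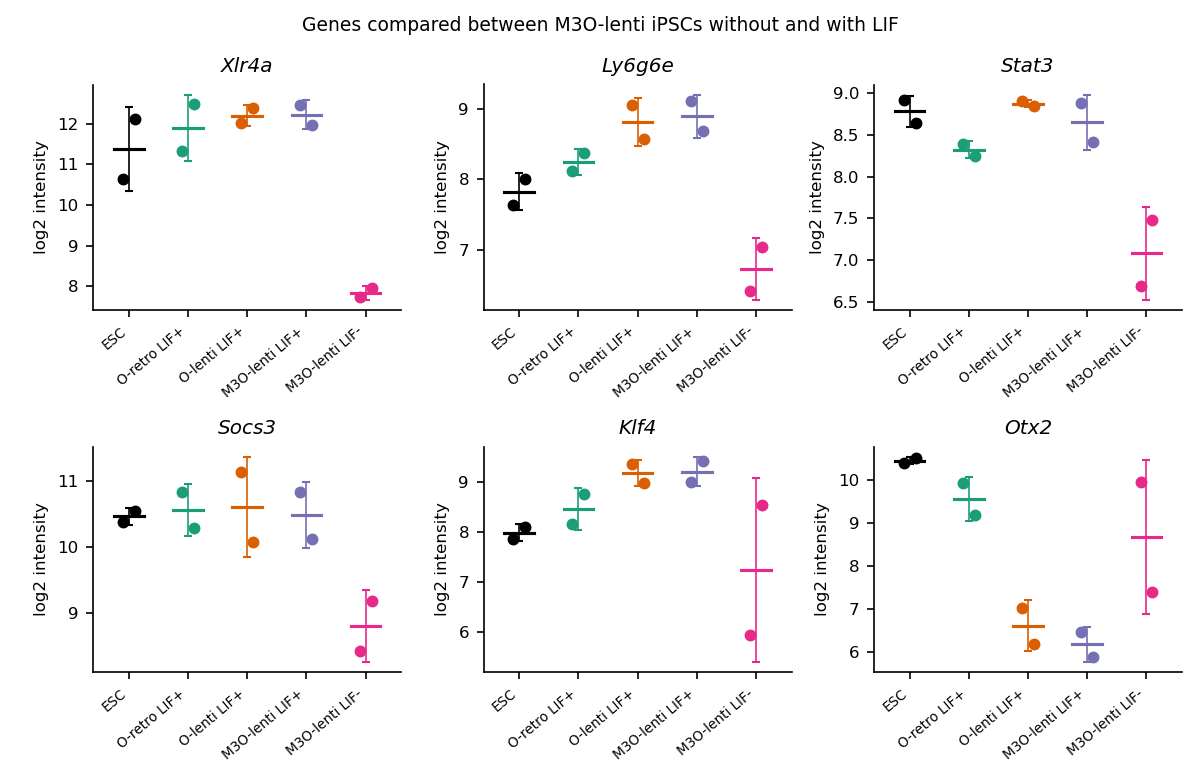
Normalized log2 intensity of 6 genes in ESCs and the 4 iPSC groups; points are single arrays, horizontal lines group means and bars 1 SD (n = 2). Xlr4a averaged 7.84 in M3O-lenti LIF- cells, against 12.21 in M3O-lenti LIF+ cells and 11.37 in ESCs.

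Several lists moved together between these groups. Markers of fibroblasts were lower without LIF in 25 of 26 genes (8 adjusted over the list alone, camera adjusted p = 7.96e-11, and adjusted p = 0.228 with an estimated correlation), among them the collagen gene Col3a1 (-1.17 ± 0.22) and the matrix protease gene Mmp2 (-1.45 ± 0.27). Genes of the primitive endoderm, an early extraembryonic layer, were lower in 14 of 15 (7 adjusted over the list alone, adjusted p = 3.98e-08, and 0.133 with an estimated correlation), as for the basement membrane collagen Col4a1 (-1.23 ± 0.20) and the regulator Gata6 (-1.20). Mesenchymal transition genes were lower in 13 of 14 (5 adjusted over the list alone, adjusted p = 7.73e-06, and 0.133 with an estimated correlation), including the TGF-beta receptor gene Tgfbr2 (-1.21 ± 0.26) and Snai1 (-1.14). Targets of LIF and STAT3 were lower in 13 of 22 (6 adjusted over the list alone, adjusted p = 0.00191, and 0.228 with an estimated correlation), while the list of LIF receptor and JAK-STAT components was higher in 11 of 18 and did not pass (adjusted p = 0.736), with a median of 0.07, a mean of -0.09 and a negative test direction. ER and amino acid stress genes were lower in 17 of 22 (adjusted p = 0.0029, and 0.138 with an estimated correlation). The 5 lists that passed did so also without each array in turn; no member passed over all genes, although Mmp2 (-1.76) and Col4a1 (-1.39) did without LIF- B (adjusted p = 0.0479 for both).

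The other lists that passed rested on single arrays. Primed epiblast genes were higher without LIF in 11 of 11 (adjusted p = 7.73e-06, and 0.499 with an estimated correlation; 0.224 without LIF- A). Epithelial junction genes, among them the splicing regulator Esrp1 (2.51 ± 0.59, and 3.57 with an adjusted p of 0.017 without LIF- B), were higher in 14 of 17 (0.00243, and 0.517 with an estimated correlation; 0.0796 without LIF- A). Glycolysis genes such as Tpi1 (1.13, and 2.04 with an adjusted p of 0.022 without LIF- B) were higher in 13 of 16 (0.00243, and 0.587 with an estimated correlation; 0.848 without LIF- A). Oxidative phosphorylation genes were lower in 19 of 23 (0.0029, and 0.521 with an estimated correlation; 0.0676 without LIF- A and 0.12 without LIF+ B). Endothelial genes were higher in 8 of 9 (0.0494, and 0.290 with an estimated correlation; 0.206 without LIF+ A, 0.148 without LIF- A, 0.09 without LIF- B, 0.105 with quantile normalization alone and 0.09 with the submitters' matrix). Naive pluripotency genes were lower in 12 of 19 and did not pass (adjusted p = 0.161; 0.00652 without LIF- B). Core pluripotency genes did not pass (adjusted p = 0.994), with a median difference of 0.06, a mean of -0.05 and a negative test direction.

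**Figure D3:**
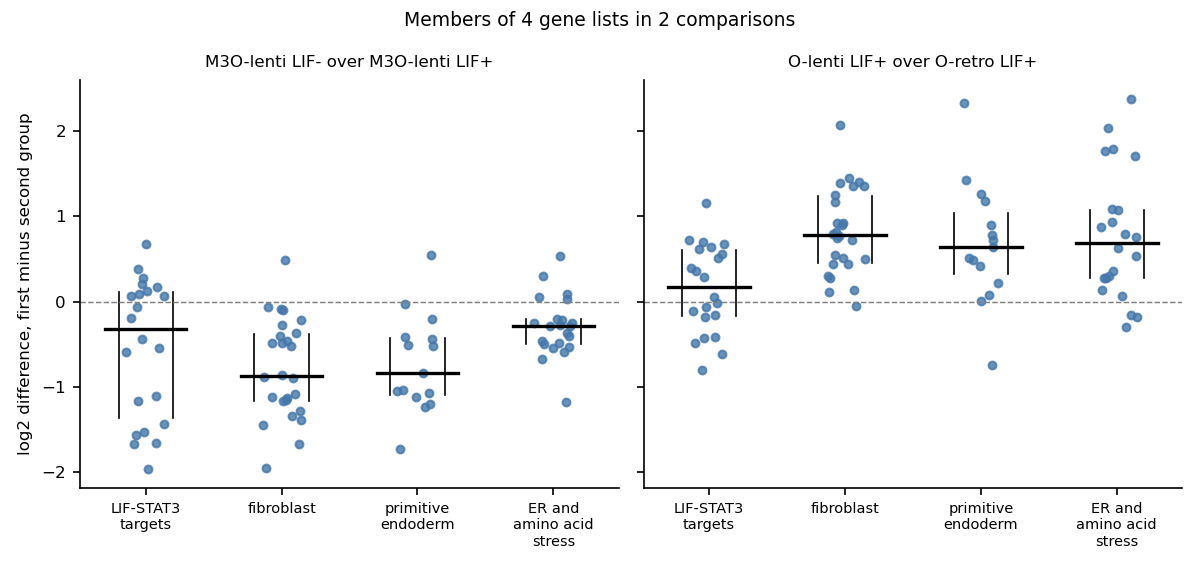
Log2 difference of each member (points) of 4 gene lists in M3O-lenti LIF- over M3O-lenti LIF+ (left) and O-lenti LIF+ over O-retro LIF+ (right), with medians (thick lines) and quartiles (thin lines). Fibroblast genes were lower in 25 of 26 on the left and higher in 25 of 26 on the right.

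Set against the mean of the 3 LIF+ iPSC types, M3O-lenti LIF- cells had lower Stat3 (-1.53 ± 0.23, adjusted p = 0.046). Xlr4a fell by 4.26 ± 0.38 (adjusted p = 0.00323), as did Ly6g6e (-1.92 ± 0.22, adjusted p = 0.0141), Rcsd1, which encodes a regulator of actin capping (-2.59 ± 0.29, adjusted p = 0.0141), and the apolipoprotein gene Apom (-2.81 ± 0.39, adjusted p = 0.0396). Efhc2, an X-linked gene of ciliary microtubules, was not detected without LIF and was at least 6.16-fold lower (adjusted p = 0.0455). With quantile normalization alone, its difference came to -1.45 on the log2 scale and did not pass (0.291). In each LIF+ type 1 array lacked Y-linked signal, while both LIF- arrays had it, so the groups also differ in this. Mup6, of the major urinary protein family, rose by 1.51 ± 0.22 (adjusted p = 0.0455). Socs3 differed by -1.74 ± 0.33 (adjusted p = 0.173) and Pim3 by -1.03 (adjusted p = 0.301).

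With limma, 8 genes were called, 7 of them lower, and the call not named above is a predicted gene with a clone name. An unadjusted p under 0.05 was found for 770 genes, where chance would give 478. The excess was gone without LIF- A and larger without LIF- B, fits that leave 1 LIF- array. Each of the 7 named calls was lost without some array: without LIF- A, adjusted p was 0.0716 for Xlr4a, 0.211 for Ly6g6e, 0.0882 for Rcsd1, 0.449 for Apom, 0.589 for Efhc2, 0.435 for Mup6 and 0.698 for Stat3. Stat3 lost its call without each of the 7 arrays other than LIF- B (0.0561 to 0.698). With quantile normalization alone or the submitters' matrix, Xlr4a and Ly6g6e kept their calls and the other 5 lost them: Rcsd1 (-1.49, adjusted p = 0.11, and -1.46, 0.146), Apom (-1.79, 0.195, and -1.76, 0.235), Efhc2 (-1.45, 0.291, and -1.41, 0.318), Stat3 (-1.14, 0.11, and -1.14, 0.146) and Mup6 (1.09, 0.112, and 1.07, 0.151). Without a detection filter none of the 7 passed (0.0693 for Xlr4a, 0.112 for Ly6g6e and 0.126 to 0.337 for the others), and with only the arrays of the groups compared Xlr4a alone did (0.0815 to 0.179 for the others). The count was 1 without LIF- A, a gene not among the 8, 3 without O-lenti B, 4 without M3O-lenti LIF+ A or LIF+ B, 5 without O-lenti A, 19 without O-retro A and 39 without LIF- B.

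Primitive endoderm genes were lower in 14 of 15 (4 adjusted over the list alone, adjusted p = 1.04e-06, and 0.281 with an estimated correlation), and targets of LIF and STAT3 in 13 of 22 (6 adjusted over the list alone, 0.000292, and 0.324 with an estimated correlation). Both passed without each array in turn. Primed epiblast genes were higher in 10 of 11 (3.04e-05, and 0.559 with an estimated correlation; 0.863 without LIF- A), and epithelial junction genes in 14 of 17 (0.00142, and 0.559 with an estimated correlation; 0.183 without LIF- A). Fibroblast genes were lower in 21 of 26 (0.000292, and 0.612 with an estimated correlation; 0.183 without LIF- A) and mesenchymal transition genes in 12 of 14 (0.00291, and 0.364 with an estimated correlation; 0.0549 without LIF- B). Cholesterol synthesis (0.0369), naive pluripotency, glycolysis and oxidative phosphorylation genes (0.0403 each) also passed, and lost the call with an estimated correlation (0.614, 0.559, 0.614 and 0.614). They lost it too without LIF- B for cholesterol synthesis (0.845), without LIF- A for naive pluripotency (0.75) and oxidative phosphorylation (0.511), without O-lenti A for glycolysis (0.146), and without 2 to 5 other arrays each (0.0528 to 0.178); without LIF- A, glycolysis passed in the opposite direction (0.025).

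M3O-lenti LIF+ cells were compared with O-lenti LIF+ cells, their control, to ask what the MyoD domain changed. No gene was called with limma, nor under any alternative that kept both arrays of each group. An unadjusted p under 0.05 was found for 111 genes, fewer than the 478 that chance would give. The fit may thus be conservative here, and it does not show that the domain changed nothing. Differences between replicates A and B were partly shared by these groups (r = 0.388 across genes), which a fit without pairing counts as error. With the replicate letter as a block over the 8 iPSC arrays, the count was 168, against 126 over these arrays without the block. It was also 168 with only the arrays of the groups compared and no block. These counts thus do not show that pairing accounts for the low number. Recovery of simulated changes was not measured for this comparison. Pou5f1 differed by -0.35 ± 0.36, Sox2 by -0.38 ± 0.20, Nanog by 0.16, Klf4 by 0.03, Stat3 by -0.22 and Socs3 by -0.13, each with an adjusted p of 1. Muscle genes were higher in 4 and lower in 5 of 9 (camera adjusted p = 0.441). Fibroblast genes were higher with M3O in 21 of 26 (adjusted p = 0.000547, and 0.836 with an estimated correlation), for example Col3a1 (0.73 ± 0.22), and mesenchymal transition genes in 11 of 14 (0.0341, and 0.829 with an estimated correlation), for example Tgfbr2 (0.64). The first call was lost without M3O-lenti LIF+ A (0.46) and O-lenti B (0.0631). The other was lost without M3O-lenti LIF+ A (0.402), O-lenti A (0.211) and O-lenti B (0.102), and with the submitters' matrix (0.0687).

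Between O-lenti and O-retro cells, both with LIF, which differ in the vector that carried Oct4, genes of ER and amino acid stress were higher with the lentiviral vector in 19 of 22 (10 adjusted over the list alone, camera adjusted p = 1.34e-09). This list also passed with an estimated correlation (adjusted p = 0.016) and without each array in turn. Its members with the smallest p were the kinase-like regulator gene Trib3 (1.70 ± 0.28, adjusted p = 0.149), the lipoprotein receptor gene Vldlr (1.76 ± 0.30, 0.149), the glutathione-degrading enzyme gene Chac1 (2.04 ± 0.44, 0.222) and Herpud1 (1.08 ± 0.24, 0.222), none of which passed over all genes. With limma, no gene was called, 912 had an unadjusted p under 0.05, and the smallest adjusted p was 0.149; without O-lenti B, 4 genes were called, among them Vldlr (0.0282).

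Fibroblast genes such as Mmp2 (1.40 ± 0.27) were higher in 25 of 26 in O-lenti cells (7 adjusted over the list alone, adjusted p = 6.01e-11, and 0.224 with an estimated correlation). Primitive endoderm genes such as Col4a2 (1.18 ± 0.21) and Lama1 (2.33 ± 0.58) were higher in 14 of 15 (7 adjusted over the list alone, 2.89e-06, and 0.168 with an estimated correlation), and mesenchymal transition genes such as Tgfbr2 (1.13) in 11 of 14 (0.00313, and 0.224 with an estimated correlation). These passed without each array in turn. Glycolysis genes such as Pfkl (-1.57) were lower in 13 of 16 (0.000118, and 0.517 with an estimated correlation; 0.0791 without O-retro A), and primed epiblast genes, led by Otx2 (-2.95 ± 0.64), in 10 of 11 (0.00525, and 0.664 with an estimated correlation; 0.222 without O-retro A). Without O-lenti A, 4 further lists lost their call: DNA and histone methylation (18 of 22 lower; 0.00525, and 0.384 with an estimated correlation; 0.306), cell cycle (19 of 21 lower; 0.00531, and 0.168 with an estimated correlation; 0.0804), cholesterol synthesis (13 of 16 lower; 0.0181, and 0.664 with an estimated correlation; 0.802) and mesoderm (6 of 8 lower; 0.0274, and 0.517 with an estimated correlation; 0.261). The last 2 also lost it without O-retro B, where the mesoderm median went from -0.562 to 0.0646. Without O-lenti A, the cholesterol synthesis median went from -0.354 to -0.00729. Mesoderm lost its call too with quantile normalization alone (0.0524) and the submitters' matrix (0.0556). Stat3 (0.55), Socs3 (0.05), Klf4 (0.72), Pou5f1 (0.17), Nanog (0.08) and Sox2 (-0.13) did not pass.

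Each iPSC type was compared with ESCs to ask how close it came to them. Supt16, which encodes a histone chaperone subunit, rose by 4.85, 4.75, 4.48 and 4.87 (each ± 0.18) in O-retro, O-lenti, M3O-lenti LIF+ and M3O-lenti LIF- cells. Cops8, a subunit gene of the COP9 signalosome, rose by 4.63, 4.50, 4.35 and 4.39 (each ± 0.28) in the same order. Necap2, an endocytosis gene, was not detected in ESCs and was at least 13.1-, 14.9-, 13.6- and 12.8-fold higher, and the cell cycle regulator gene Rgcc at least 24.5-, 20.3-, 20.3- and 11.3-fold higher. Pou5f1 fell, with differences of -3.14, -2.98, -3.33 and -3.17 (each ± 0.36, adjusted p = 0.000754, 0.00112, 0.000559 and 0.000724). Whether its probe reads the transgenes is not known here. Atf4, the transcription factor gene of amino acid stress, rose by 2.05, 2.80, 2.74 and 2.24 (each ± 0.21; adjusted p = 0.000492, 5.98e-05, 7.09e-05 and 0.000324). These calls were kept without each array in turn. Another detected probe of Pou5f1 gave a mean difference of -3.16 and one of Atf4 gave 5.23, while one of Supt16 gave 0.70 and one of Necap2 gave 0.51, and Cops8 and Rgcc had no other detected probe.

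In O-retro cells, 362 genes were called, 226 higher and 136 lower than in ESCs. The oligodendrocyte factor gene Olig1 was at least 13.4-fold higher. The pluripotency marker gene Zfp42 fell by 3.06 ± 0.27, and the endosomal gene Wdfy1 (-2.87) and the chaperone gene Clgn (-3.20) fell too. Slc46a3, a lysosomal transporter gene, fell by 3.39 and lost its call without ESC 2 (adjusted p = 0.0871) and O-retro B (0.0825). With only the arrays of the groups compared, Clgn (0.0686) and Rhox9 (0.0509) did not pass. Trophectoderm genes, of the layer that forms the placenta, were higher in 10 of 10 (2 called, 6 adjusted over the list alone, camera adjusted p = 4.46e-05, and 0.163 with an estimated correlation), including Tfap2c (1.92 ± 0.28). Germline and 2-cell embryo genes passed (10 of 13 higher, 3 called, 4 adjusted over the list alone, 0.0426, and 0.987 with an estimated correlation), with Rhox6 (3.32 ± 0.43) and Rhox9 (3.64 ± 0.51), but not without ESC 1 (0.292) or O-retro A (0.0584). Mesoderm genes also passed (6 of 8 higher, 1 called, 3 adjusted over the list alone, 0.0426, and 0.987 with an estimated correlation), but not without ESC 1 (0.0843), ESC 2 (0.079) or O-retro B (0.649). Neither list passed with quantile normalization alone (0.0755 and 0.0808) or with the submitters' matrix (0.166 and 0.197). The count was 240 without ESC 1, 149 without ESC 2 and 158 without O-retro B.

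In O-lenti cells, 711 genes were called, 399 higher and 312 lower. Ubap1l, a gene of ubiquitin binding, rose by 4.15 ± 0.53. Clgn (-3.72), Otx2 (-3.85 ± 0.64) and the Nodal inhibitor gene Lefty1 (-4.08 ± 0.85) fell, and Ankrd37 and Slc46a3 were not detected and at least 15.3- and 10.3-fold lower. Without ESC 2, Otx2 (adjusted p = 0.057), Lefty1 (0.158), Ankrd37 (0.121) and Slc46a3 (0.0606) lost their calls. Without O-lenti B, Otx2 (0.0511), Lefty1 (0.0991) and Ankrd37 (0.0646) lost it, and without O-lenti A, Lefty1 (0.066), Ankrd37 (0.0881) and Slc46a3 (0.0509); without a detection filter, Lefty1 (0.071) and Ankrd37 (0.0589) lost it. ER and amino acid stress genes such as Trib3 (2.56 ± 0.28) were higher (17 of 22, 9 called, 11 adjusted over the list alone, camera adjusted p = 2.93e-05, and 0.0799 with an estimated correlation), as were primitive endoderm genes (15 of 15; 5 called, 11 adjusted over the list alone, 4.19e-07, and 0.103 with an estimated correlation), trophectoderm genes (10 of 10; 2 called, 7 adjusted over the list alone, 0.000222, and 0.103 with an estimated correlation) and fibroblast genes (24 of 26; 1 called, 1 adjusted over the list alone, 0.000222, and 0.7 with an estimated correlation). Primed epiblast genes were lower in 11 of 11 (1 called, 4 adjusted over the list alone, 0.0014, and 0.811 with an estimated correlation), and glycolysis genes were lower (13 of 16, 4 called, 6 adjusted over the list alone, 0.00249, and 0.819 with an estimated correlation). Germline and 2-cell embryo genes were higher (11 of 13, 4 called, 5 adjusted over the list alone, 0.0236, and 0.689 with an estimated correlation), but not without ESC 1 (0.241) or O-lenti A (0.061), with quantile normalization alone (0.0513) or with the submitters' matrix (0.1). Of the called members, Rhox6 (1.95, 0.0238) and Rhox9 (2.08, 0.0341) lost their calls without any 1 of the 4 arrays (0.0961 to 0.101 and 0.109 to 0.136). They also lost them with quantile normalization alone (0.95, 0.123, and 1.37, 0.104), with the submitters' matrix (0.927, 0.145, and 1.38, 0.124) and without a detection filter (0.0727 and 0.102). The count was 453 without ESC 1, 184 without ESC 2, 239 without O-lenti A and 313 without O-lenti B.

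In M3O-lenti LIF+ cells, 782 genes were called, 464 higher and 318 lower. Twistnb, a gene of RNA polymerase I, was not detected in ESCs and was at least 15.1-fold higher. Another detected probe of Twistnb gave a mean difference of 2.97 over the iPSC types. Otx2 fell by 4.28 ± 0.64 (adjusted p = 0.00398), and Clgn and Slc46a3 were not detected and at least 11.9- and 10.8-fold lower. Lefty1 (-3.88 ± 0.85) and Ankrd37 (-3.46 ± 0.82) fell as well. Without ESC 2, adjusted p was 0.0563 for Slc46a3, 0.168 for Lefty1 and 0.195 for Ankrd37; Lefty1 was also lost without M3O-lenti LIF+ B (0.156), and Ankrd37 without ESC 1 (0.0625), LIF+ A (0.148) and LIF+ B (0.125). Nanog, higher by 1.48 ± 0.39 (adjusted p = 0.0422), lost its call without any 1 of the 4 arrays (0.0765 to 0.242), with the submitters' matrix (0.0636) and without a detection filter (0.111). It was higher than in ESCs in the other types too, and did not pass: 1.25 in O-retro (0.105, and 0.0266 without O-retro A), 1.32 in O-lenti (0.0632, 0.0364 with only the arrays of the groups compared and 0.0496 with a trended and robust variance) and 0.71 in M3O-lenti LIF- cells (0.373). Ankrd37 also lost its call with the submitters' matrix (-2.14, 0.0514) and without a detection filter (0.102), and Lefty1 without a detection filter (0.0829). The lists that passed, each without every single array too, were fibroblast genes (24 of 26 higher, 7 called, 13 adjusted over the list alone, camera adjusted p = 6.87e-07, and 0.47 with an estimated correlation), primitive endoderm genes (14 of 15 higher, 7 called, 10 adjusted over the list alone, 8.99e-07, and 0.152 with an estimated correlation) and ER and amino acid stress genes such as Trib3 (2.23 ± 0.28; 16 of 22 higher, 9 called, 10 adjusted over the list alone, 9.24e-05, and 0.113 with an estimated correlation). They also included trophectoderm genes (10 of 10 higher, 3 called, 5 adjusted over the list alone, 0.00158, and 0.193 with an estimated correlation) and mesenchymal transition genes such as Tgfbr2 (1.89 ± 0.26; 12 of 14 higher, 3 called, 5 adjusted over the list alone, 0.00278, and 0.281 with an estimated correlation). Primed epiblast genes were lower in 11 of 11 (1 called, 4 adjusted over the list alone, 0.00154, and 0.783 with an estimated correlation), and glycolysis genes were lower (14 of 16, 3 called, 7 adjusted over the list alone, 0.00154, and 0.783 with an estimated correlation). The count was 447 without ESC 1, 183 without ESC 2, 159 without LIF+ A and 201 without LIF+ B.

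In M3O-lenti LIF- cells, 409 genes were called, 253 higher and 156 lower than in ESCs. Stat3 fell by 1.69 ± 0.28 (adjusted p = 0.00741, 0.0539 without ESC 1 and 0.078 with only the arrays of the groups compared). Socs3 fell by 1.66 ± 0.41 (adjusted p = 0.0484), a call lost without any 1 of the 4 arrays (0.0854 to 0.26), with quantile normalization alone (0.0608), with the submitters' matrix (0.0641), without a detection filter (0.13) and with only the arrays of the groups compared (0.0769). In the 3 LIF+ types, Stat3 differed from ESCs by -0.46, 0.09 and -0.13 and did not pass. Xlr4a fell by 3.53 ± 0.46 (adjusted p = 0.00217), as did the homeobox gene Rhox10 (-2.98 ± 0.45, adjusted p = 0.0883 with only the arrays of the groups compared), Zfp42 (-3.19 ± 0.27) and Wdfy1 (-2.88). Wdr82, of a histone methyltransferase complex, was at least 10.3-fold higher, although another detected probe gave a mean of -0.65 over the iPSC types, and Olig1 was at least 11.2-fold higher. Trophectoderm genes were higher in 10 of 10 (1 called, 5 adjusted over the list alone, camera adjusted p = 0.000618, and 0.192 with an estimated correlation). The called member, Tfap2c (1.27, adjusted p = 0.035), lost its call without any 1 of the 4 arrays (0.126 to 0.132), without a detection filter (0.0704) and with only the arrays of the groups compared (0.0614). ER and amino acid stress genes such as Trib3 (1.64 ± 0.28; lost without ESC 1, 0.0519, ESC 2, 0.0735, or LIF- B, 0.0929) were higher (16 of 22, 5 called, 7 adjusted over the list alone, 0.0105, and 0.192 with an estimated correlation; 0.14 without ESC 1), and cholesterol synthesis genes lower (14 of 16, 1 called, 2 adjusted over the list alone, 0.0343, and 0.993 with an estimated correlation), but not without ESC 1 (0.14) or LIF- B (0.471). The count was 221 without ESC 1, 137 without ESC 2 and 123 without LIF- B.

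Tfcp2l1, a LIF target that maintains naive pluripotency, rose in O-retro (2.00, adjusted p = 0.0467), O-lenti (2.70, 0.00916) and M3O-lenti LIF+ cells (2.65, 0.0105), while in M3O-lenti LIF- cells it differed by 1.55 (0.107) and passed without ESC 1 (2.30, 0.037). Without ESC 2, these 3 calls were lost (0.297, 0.0726 and 0.0764). The first was also lost without O-retro A (0.0599) and B (0.279), with quantile normalization alone (0.0546), without a detection filter (0.128) and with only the arrays of the groups compared (0.157), the second without O-lenti A (0.0622) and the third without M3O-lenti LIF+ A (0.074) and B (0.0672). Whether the difference from ESCs itself differed with LIF was tested between the M3O-lenti groups, where Tfcp2l1 did not pass (-1.10 ± 0.48, adjusted p = 0.555).

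**Figure D4:**
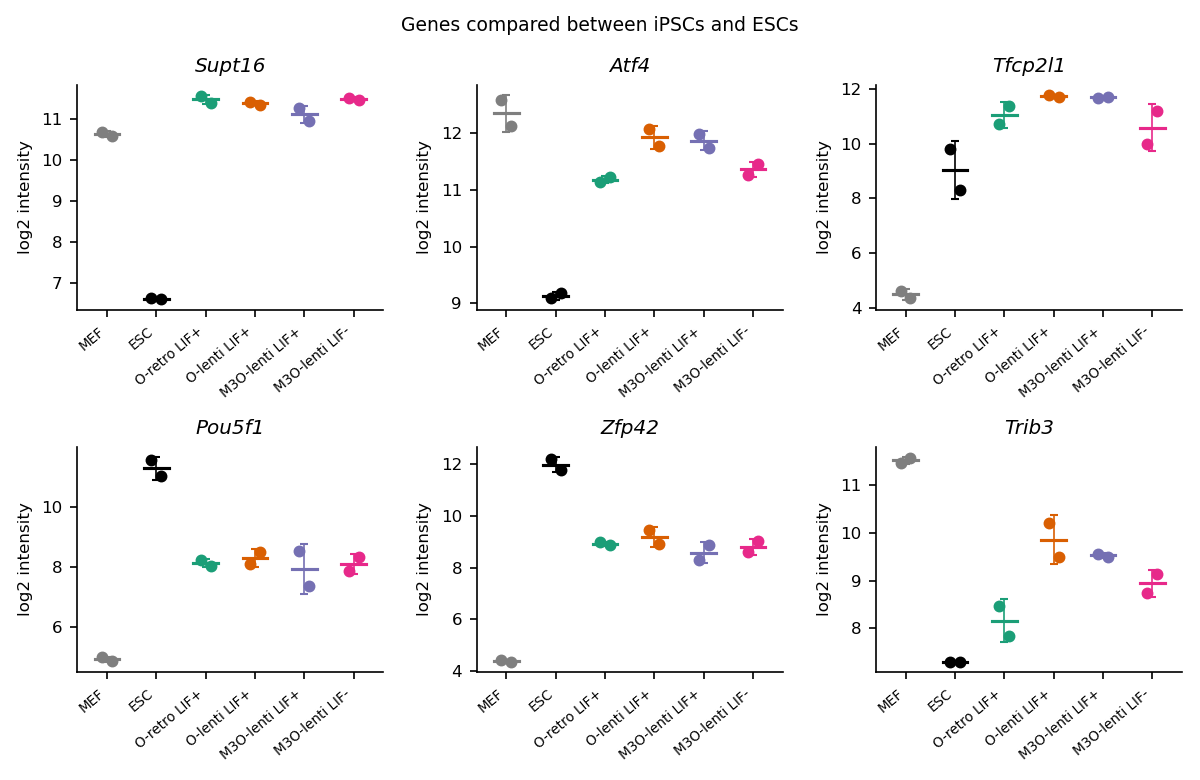
Normalized log2 intensity of 6 genes in all 6 groups; points are single arrays, horizontal lines group means and bars 1 SD (n = 2). Supt16 averaged 6.63 in ESCs and 11.12 to 11.50 in the iPSC groups, and Pou5f1 averaged 11.28 in ESCs and 7.95 to 8.30 in the iPSC groups.

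Genes lower in iPSCs than in ESCs were often on chromosome 8. That chromosome held 5.41% of the genes tested, but 25 of 136 lower genes in O-retro cells, 64 of 312 in O-lenti cells, 70 of 318 in M3O-lenti LIF+ cells and 27 of 156 in M3O-lenti LIF- cells. Zfp42, Clgn and Ankrd37 are among them. Over 290 genes of chromosome 8 with a mean log2 intensity above 7, the median difference from the iPSC median was 0.414 on ESC 1 and 0.482 on ESC 2. Over 426 genes of chromosome 11, it was 0.045 on ESC 1 and 0.451 on ESC 2.

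**Figure D5:**
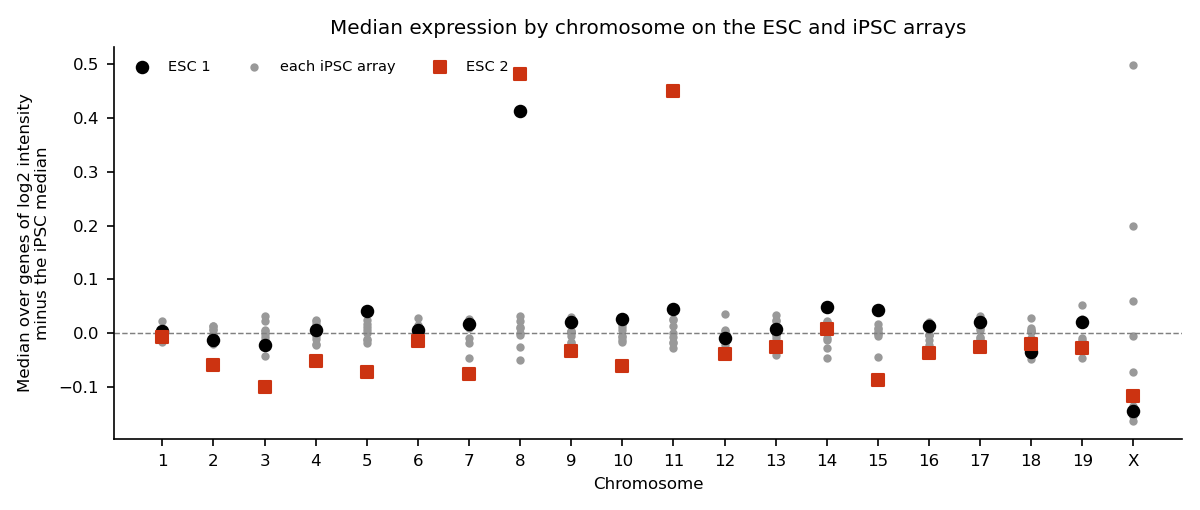
Median over each chromosome's genes of log2 intensity minus the iPSC median, for ESC 1 (black circles), ESC 2 (red squares) and each iPSC array (grey). Chromosome 8 lay at 0.414 and 0.482 on the ESC arrays, and chromosome 11 at 0.045 and 0.451.

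ESCs were compared with MEFs to measure the distance between pluripotent cells and fibroblasts. Dppa5a, a pluripotency marker, was not detected in MEFs and was at least 681-fold higher in ESCs, and Dppa4 at least 183-fold, Zfp42 at least 126-fold, the hormone gene Trh at least 142-fold and the homeobox gene Rhox5 at least 130-fold higher. Pou5f1, Nanog and Sox2 were at least 76.6-, 42.3- and 16.2-fold higher, and the epithelial cadherin gene Cdh1 rose by 4.53 ± 0.23. The chemokine gene Cxcl10 and the innate immunity gene Ptx3 were at least 57.8- and 52.9-fold lower, and the lysozyme genes Lyz1 (-6.15 ± 1.22) and Lyz2 (-6.07 ± 1.06), the smooth muscle actin gene Actg2 (-5.96 ± 0.22), Thy1 (-5.30 ± 0.41) and the collagen gene Col1a1 (-3.52 ± 0.35) fell. Myc was at least 3.76-fold lower. Klf4 (-0.09, adjusted p = 0.913) and Stat3 (-0.06, adjusted p = 0.871) did not pass, and Socs3 rose by 2.42 ± 0.41. With limma, 5289 genes were called, 2817 higher and 2472 lower, 3636 of them by at least 2-fold; the named calls passed without each array in turn. Core pluripotency genes were called higher in 19 of 19 (camera adjusted p = 8.63e-15, and 0.0337 with an estimated correlation). Mesenchymal transition genes were called lower in 14 of 14 (1.74e-07, and 0.0344 with an estimated correlation), including Snai2 and Zeb2, at least 46.1- and 18.0-fold lower. Fibroblast genes were called lower in 23 of 26 (24 adjusted over the list alone, 1.22e-11, and 0.131 with an estimated correlation) and naive pluripotency genes higher in 13 of 19 (8.64e-05, and 0.113 with an estimated correlation).

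The 4 iPSC types together were compared with the MEFs from which such cells are made. Dppa5a was at least 804-fold, Rhox5 at least 341-fold, the egg and embryo gene Ooep at least 176-fold, the naive pluripotency factor gene Esrrb at least 175-fold and Dppa4 at least 167-fold higher, and Pou5f1, Nanog and Sox2 at least 8.59-, 96.6- and 17.9-fold higher. Cxcl10 and Ptx3 were at least 58.5- and 53.6-fold lower, and Actg2 (-5.65 ± 0.18), the caveolar gene Cavin2 (-5.55 ± 0.32), the mesenchymal factor gene Twist2 (-5.52 ± 0.41), Thy1 (-4.73 ± 0.32) and Col1a1 (-3.36 ± 0.28) fell. Cdh1 rose by 4.36 ± 0.18 and Socs3 by 2.07 ± 0.32, and Klf4 did not pass (0.44, adjusted p = 0.455), except without M3O-lenti LIF- A (0.767, 0.0127). Stat3 fell by 0.61 ± 0.22 (adjusted p = 0.0338), a call lost without MEF 1 (0.0531), MEF 2 (0.245), O-retro B (0.0525), O-lenti B (0.0522) or M3O-lenti LIF+ B (0.0589), or without a detection filter (0.0637). Its mean was 8.84 in MEFs, against 8.32 in O-retro, 8.87 in O-lenti, 8.65 in M3O-lenti LIF+ and 7.09 in M3O-lenti LIF- cells, so the fall came mostly from the last type. With limma, 5650 genes were called, 2955 higher and 2695 lower, 3200 of them by at least 2-fold. Core pluripotency genes were called higher in 19 of 19 (camera adjusted p = 1.67e-14, and 0.0324 with an estimated correlation) and naive pluripotency genes in 16 of 19 (5.06e-06, and 0.0733 with an estimated correlation). Fibroblast genes were called lower in 24 of 26 (25 adjusted over the list alone, 1.83e-10, and 0.159 with an estimated correlation) and mesenchymal transition genes in 13 of 14 (3.72e-07, and 0.0385 with an estimated correlation).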

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

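Alternatives without the 3 arrays that lacked Y-linked signal (M3O-lenti LIF+ A, O-retro B and O-lenti B) and without the 2 dimmest arrays (O-retro B and O-lenti B) were chosen after seeing the data. Of the values of named genes under all alternatives, 2552 kept their side of the threshold, 200 lost their call and 14 gained one. Of those of lists, 744 kept it, 147 lost it, 3 gained it and 4 turned direction. A gene or list that passed in neither fit counts as kept, whatever its direction, so these numbers do not measure how many calls held. Counts for M3O-lenti LIF- over LIF+ (2) and over the 3 LIF+ types (8) were 0 (769 at an unadjusted p under 0.05) and 2 with quantile normalization alone, 0 (794) and 2 with the submitters' matrix, 0 (1293) and 0 (1220) with no detection filter in limma, 1 and 1 (Xlr4a in both) with the 8 iPSC arrays alone, and 1 and 1 without the 3 arrays, where the first is neither of the 2 genes called with all arrays. The first was 5, all lower, with a trended and robust variance, and the second 1 with only the groups compared and 3 without the 2 dimmest arrays. With only the groups compared, which leaves 2 residual degrees of freedom, O-retro, O-lenti and M3O-lenti LIF- differed from ESCs in fewer genes (126, 470 and 109) and M3O-lenti LIF+ in more (1038). Without the 3 arrays, O-retro, O-lenti and M3O-lenti LIF+ differed from ESCs in 84, 159 and 120, and without the 2 dimmest, O-retro and O-lenti in 137 and 304, with fewer arrays in each. A 2-fold minimum left 3200 genes for iPSCs over MEFs. Leaving out each array gave 0 to 48 genes for M3O-lenti LIF- over LIF+, 1 to 39 over the 3 LIF+ types, 0 to 4 for O-lenti over O-retro, 0 throughout for M3O-lenti over O-lenti, 149 to 401, 184 to 453, 159 to 447 and 123 to 291 for O-retro, O-lenti, M3O-lenti LIF+ and M3O-lenti LIF- over ESCs, 4237 to 4639 for ESCs over MEFs and 4484 to 5598 for iPSCs over MEFs. The test's direction turned without M3O-lenti LIF- A for glycolysis against LIF+ (median 0.0315, adjusted p = 0.848, medians 0.0315 to 1.04 without each array), and against the 3 types for glycolysis (-0.191, 0.025, range -0.191 to 0.779) and primed epiblast (-0.042, 0.863, range -0.042 to 1.26), and without LIF- B for cholesterol synthesis (0.129, 0.845, range -0.561 to 0.129). Except for fewer arrays, the cause was not tested. No normalization moved the share of higher genes by more than 10 points in counts above 8. The replicate letters did not meet the criterion for pairing, a correlation of deviations above 0.1 in every pair of groups: 3 of 6 pairs reached it (-0.0379 to 0.388). As a hint of shared handling that leaves pairing open, 7 of 8 arrays matched best with an array of their own letter. With the letter as a replicate block, M3O-lenti LIF- over LIF+ gave 1 gene and over the 3 types 1 (Xlr4a in both), M3O-lenti over O-lenti 0 (168 at an unadjusted p under 0.05) and O-lenti over O-retro 0 (1084). With an estimated correlation, 1 of 10 lists kept its call for O-lenti over O-retro, 4 of 15 for ESCs over MEFs and 4 of 13 for iPSCs over MEFs, and none did elsewhere. Slide as a block was not run, since the files used here name no slides. Genes near background were limited by signal: a gene whose chosen probe was not detected in a group has only a bound for that probe.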

Other observations

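Of the tests below, those of kept fibroblast expression, of primitive endoderm cells and of uneven normalization were chosen only after the result was seen.

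Immune genes separated MEFs from the pluripotent cells. Interferon and antigen presentation genes were called lower than in MEFs in 14 of 18 in ESCs (camera adjusted p = 0.000194, and 0.541 with an estimated correlation) and in 15 of 18 in iPSCs (2.73e-05, and 0.422 with an estimated correlation). B2m, the light chain of MHC class I, fell in both comparisons (-3.92 ± 0.33 and -3.46 ± 0.26), as did the interferon-induced Isg15 (-5.83 ± 0.98 and -5.32 ± 0.78). Macrophage genes were called lower in 8 and 9 of 11 (0.000192, and 0.169 with an estimated correlation; 0.000896, and 0.237 with an estimated correlation); the receptor subunit gene Fcer1g was at least 17.7- and 17.9-fold lower. ER and amino acid stress genes were called lower in 16 and 14 of 22 (1.77e-06 and 1.81e-05, and 0.0337 and 0.0324 with an estimated correlation), with the stress factor gene Ddit3 changed by -4.85 ± 0.26 and -4.54 ± 0.21. Cell cycle genes were called higher in 17 of 21 in both (2.5e-05 and 1.4e-05, and 0.0344 and 0.0324 with an estimated correlation), with the mitotic kinase gene Aurkb up by 2.27 in each. DNA and histone methylation genes were called higher in 16 and 18 of 22 (1.44e-05 and 6.38e-06, and 0.113 and 0.0803 with an estimated correlation); Tet1, a DNA demethylation enzyme gene, was at least 33.1- and 40.6-fold higher.

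The Y-linked gene Eif2s3y was at 4.64 on M3O-lenti LIF+ A, 4.47 on O-retro B and 4.26 on O-lenti B, against 8.68 to 9.15 on the other ESC and iPSC arrays and 6.68 and 6.90 on the MEF arrays. Xist was at 9.73 and 9.11 in MEFs and at 4.30 to 5.70 elsewhere. Over 150 X-linked genes, the median difference from the iPSC median was 0.199, 0.499 and 0.059 on those 3 arrays.

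The differences between ESCs and iPSCs were shared by the 4 iPSC types: 207 genes were called in all 4 comparisons with 1 sign, 132 higher and 75 lower in iPSCs. In 100 simulations of noise alone, with simulated ESC arrays shared by the 4 comparisons, that count had a median of 0 and a highest value of 0. Without any effect the adjustment calls almost no gene, so this outcome was all but set in advance. It does not show how many shared calls the measured ESC arrays bring. Independent lists would give 0.0122 higher and 0.00242 lower genes. The ESC group can only be split into single arrays, so part of the excess over independent lists may come from the shared ESC arrays. Of these genes, 76 differed by at least 4-fold. A strain difference under single probes was tested on the 21 of them with another detected probe: 33.3% (14.6 to 57, exact 95% limits) had one that differed by under 2-fold, against 13.5% (10.2 to 17.4) of 371 genes set apart between iPSCs and MEFs, so a variant may account for some genes and the limits leave its share open. Of the 55 higher genes, 52.7% (38.8 to 66.3) had a MEF level past the midpoint between ESCs and iPSCs, which leaves open whether iPSCs kept fibroblast expression; MEF RNA and strain were not separated, since the strains of the cells are not given in the sources used here.

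Fibroblast markers were lower in M3O-lenti LIF- than in LIF+ cells. RNA from feeder fibroblasts was a candidate explanation, since the labels name feeders for the LIF+ cells. The 50 brightest MEF genes outside the lists were taken from genes called much lower in ESCs than in MEFs. The 26 fibroblast markers were not filtered in this way. Of the 50 genes, 45 fell, with a median log2 difference of -0.735. Their linear difference had a median of 3.39% (2.4 to 4.05) of the MEF level, against 7.05% (3.29 to 19) for the markers. These bootstrap 95% limits came from resampling genes, which may vary together, and hold no spread between arrays. The 3.39% is under the share set in advance for feeders alone and above the one that would have excluded them. Both shares were fractions of a marker median with wide limits, so feeder RNA stays open. ESCs and O-retro cells were also grown on feeders, yet the list had a median over ESCs of -0.0918 in O-retro (-0.367 without ESC 2, where it passed as lower, adjusted p = 0.0306) and -0.047 in M3O-lenti LIF- cells. It was higher in O-lenti than in O-retro cells in 25 of 26 genes (median 0.777). The markers thus differed between groups that were all labelled as grown on feeders. No groups known to differ only in feeders were compared, and the amount of feeder RNA in each culture was not measured. Primitive endoderm cells in the LIF+ cultures stay open too. In that list, the 7 genes that encode no matrix protein or its chaperone had a median of -1.03, with 6 of 7 lower (-1.12 to -0.0277, bootstrap 95% limits over genes). The value met the bound written for such cells, but that test was chosen after the whole list had been seen lower in the same comparison, so it could have argued against such cells but not for them. LIF itself, in which the M3O-lenti groups also differ, stays an untested biological explanation for these cells. Low values also occurred with LIF, since O-retro cells had the fibroblast median above and a primitive endoderm median over ESCs of 0.251, against 0.155 in M3O-lenti LIF- cells (0.388 without LIF- A, where it passed as higher, adjusted p = 0.0396).

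Chromosome 8 genes were brighter on both ESC arrays, and chromosome 11 genes on ESC 2. If an extra copy were the source, the shift would run along the whole chromosome: 8 of 8 consecutive runs of chromosome 8 genes had a median above 0.1 on both ESC arrays, and 8 of 8 runs of chromosome 11 genes did so on ESC 2, against 2 of 8 on ESC 1. Uneven normalization would move other chromosomes as well; the largest median of another autosome was 11.5% of that of chromosome 8 on ESC 1 and 20.7% on ESC 2, which argues against it. Extra copies in the ESC cultures are thus a candidate explanation for part of the genes lower in iPSCs, one that expression alone cannot settle. Zfp42 and Clgn, both on chromosome 8, differed by a mean of -3.12 and -3.36 over the iPSC types. The chromosome 8 medians were 0.414 and 0.482 on the ESC arrays, so a shift of that size would not account for these 2 genes. No biological alternative, such as a difference between the ESC lines and all iPSCs in regulation of these chromosomes, was tested.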
